A study of Glycine max with 6 samples.

How the data were processed

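RNA-seq of trifoliolate leaves of soybean plants aged 30 days gave 6 libraries, 3 labelled DN50 (wild type, per the labels) and 3 labelled GmRAV1-ox (genotype GmRAV1, per the labels). Replicate numbers 1 to 3 occur in both groups. Each library came with a deposited table that lists genes with a coding length, an expected count and an FPKM value, per the file headers. Expected counts are estimated counts per gene, as deposited, and between 29.7% and 30.5% of those above 0 are not whole numbers. A deposited whole-series table repeats the FPKM values with KEGG, GO and protein descriptions, and its FPKM values equalled those of the library tables (largest difference 0). TopHat and Cufflinks are named per the submitters' processing notes. Genome build, annotation release and tool versions are not given in the sources used here. All listed lengths are multiples of 3. Genes a library table does not list were set to 0.

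Counts were rounded to whole numbers, since roughly 30% were fractional. The plan made before the data were examined named limma on log2 FPKM as the test, to be replaced by edgeR if whole-number counts came with the FPKM. The counts are expected counts, so that condition was not met to the letter, and edgeR was used because counts, whole or estimated, suit a count model better than FPKM does. Limma on FPKM is given as an alternative. Robust estimation was carried over from the planned limma fit. Also set before the data were examined were the 38 gene lists, the rule for naming genes, the thresholds and most alternatives.

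In R 4.3.3, genes were filtered with filterByExpr of edgeR 4.0.16, which left 26272 of 36827. Library factors came from TMM and ranged from 0.849 to 1.17. Differences were tested with the quasi-likelihood F test with robust estimation, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Intervals are 95% intervals from the fitted log2 fold change, its standard error (the absolute log2 fold change over the square root of F) and the t distribution. Those called counting intervals instead rest on counts summed over each group, so they leave out the spread between libraries. Gene lists with at least 5 tested members (35 of 38) were tested with camera of limma 3.58.1, at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list, and fry, were run beside it. Members were also adjusted over the list alone. Principal components and correlations used log2 CPM with a prior count of 2.

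Genes were named by rule. The rule took every RAV family gene, the 10 largest and 10 smallest log2 fold changes among called genes with nonoverlapping groups, an informative description and a mean FPKM of at least 5 in the higher group, cytokinin genes past the threshold or the 3 with the smallest p, and up to 4 called members of each other list. Genes outside this rule are said to have been chosen after their values were seen. Lists were matched to the deposited descriptions, which 66% of gene identifiers carry in an informative form. Some patterns matched unrelated genes: the meristem pattern also takes in words such as vesicle, particle and cycle, the ERF pattern mTERF proteins, the abscisic acid pattern some other protein phosphatases 2C, the cytokinin synthesis pattern glycinol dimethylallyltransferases, and the list of cytokinin receptors and phosphotransfer proteins includes 2 CRF2-like ethylene-responsive factors. The lists were kept as fixed, and a corrected meristem list was added. The RAV pattern missed the gene described as a RAV-like DNA-binding protein, which was added after the data were seen. The reference table of gene names follows assembly Glycine_max_v4.0 and served only for names and neighbours, with 29456 of 36827 identifiers (80%) matched. The symbol RAV1 was tied to Glyma01g22260.1 only through its 6 matched neighbours, 2 before and 4 after.

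Library totals lay between 7208496 and 7684540 counts. At the depth and spread of these libraries, a simulation with known changes showed what the tests recover. It held 25844 genes past the filter for edgeR and DESeq2 and 25734 for limma. The shares recovered and falsely called depend on how many genes change, which was not varied. In the real libraries 5586 genes had an unadjusted p under 0.05 by edgeR, so these shares need not hold there. EdgeR recovered 9.68% of 93 2-fold and 78.9% of 95 4-fold changes, and 8 of its 93 calls were unchanged genes. Limma on FPKM recovered 3% and 74.2%. DESeq2 1.42.0 recovered 31.2% and 89.5%, but 32.2% of its 174 calls were unchanged genes. The simulation's limit on false calls was applied to edgeR and limma only after this share had been seen. Camera called a list shifted by 0.8 (log2) and 0 of 30 unshifted lists, but the simulated genes were drawn independently, so this says little about false calls of lists whose genes vary together. In the real libraries the 9 splits other than the labelled one called 5 to 18 lists.

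Alternatives were DESeq2 size factors, DESeq2's Wald test, no count filter, a filter at FPKM 5 in 3 libraries, the replicate number as a block, edgeR without robust estimation, limma on FPKM with pseudocounts of 1, 0.1 and 0.5, without a filter, with median-of-ratios or quantile scaling, with array weights and without trend or robust estimation, and each library left out in turn. No scaling factors, the corrected meristem list, the added RAV gene and GO terms with 20 to 300 tested members were alternatives chosen after the data were seen. Sequence-level questions, such as whether reads come from an added GmRAV1 copy, were not analysed here.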

Results

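RNA was sequenced from trifoliolate leaves of soybean (Glycine max) aged 30 days. Of the 6 libraries, 3 carried the label DN50, a soybean that the labels call wild type, and 3 carried the label GmRAV1-ox, with GmRAV1 given as the genotype. The labels do not spell out the suffix, which is read here as overexpression. The series title names GmRAV1, cytokinin and the regrowth of roots and adventitious buds as its subject. Estimated counts summed to between 7208496 and 7684540 per library, and between 32456 and 34028 genes were listed in each. No 2 libraries held the same values. The labels do not say that replicates came from separate plants, so the p-values measure only the spread between these samples. Levels are given as CPM (library-scaled counts, with TMM factors), as mean ± SD over the 3 libraries of a group. Genes are named by the identifiers and protein descriptions in the deposited tables.

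The first principal component held 62.6% of the variance between libraries. DN50 replicates 1 and 3 lay at -64.0 and -81.0 on it, and GmRAV1-ox replicates 1 and 2 lay at 71.6 and 100.1. DN50 replicate 2 lay at -10.3 and GmRAV1-ox replicate 3 at -16.6, between the other 4 on this component. The second component held 15.7% of the variance and set GmRAV1-ox replicate 3 apart, at -70.0. Across genes, the log2 values of GmRAV1-ox replicate 3 correlated more closely with each of the 3 DN50 libraries (r = 0.943, 0.939 and 0.918 for replicates 1 to 3) than with GmRAV1-ox replicate 1 (r = 0.908) or 2 (r = 0.883).

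**Figure D1:**
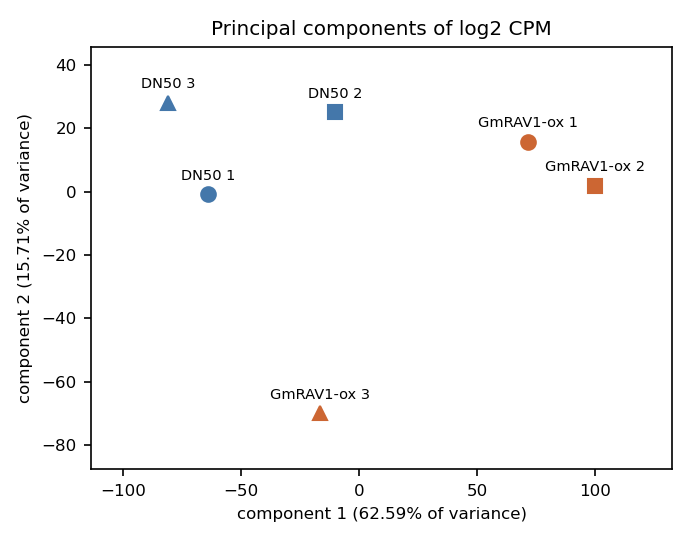
The 6 libraries on the first and second principal components of log2 CPM, with each axis giving its share of the variance. Blue points are DN50, orange points are GmRAV1-ox and each point is 1 library. GmRAV1-ox replicate 3, at -16.6 on the first component, lies on the DN50 side of the other orange points.

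Whether the RAV transcripts differed between the groups was examined first, because it checks the labels. RAV proteins carry an AP2 and a B3 DNA-binding domain and include the TEMPRANILLO repressors of flowering. None of the 3 RAV transcripts that passed the filter was higher in the libraries labelled GmRAV1-ox. Glyma01g22260.1, a TEM1-like gene, stood at 24.5 ± 5.42 in DN50 and 23.7 ± 7.32 in GmRAV1-ox, a fold of 0.967 (95% interval 0.644 to 1.45). Glyma02g11060.1, also TEM1-like, stood at 33.5 ± 12.6 and 28.01 ± 9.63, a fold of 0.834 (0.494 to 1.41). Glyma10g34760.1, described as a RAV-like DNA-binding protein, stood at 6.11 ± 3.05 and 5.99 ± 0.219, a fold of 0.975 (0.563 to 1.69).

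By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.928 for Glyma01g22260.1, 0.673 for Glyma02g11060.1 and 0.961 for Glyma10g34760.1. Adjusted over the list alone, it was 0.917 for each. Of these 3 genes, 0 passed at an unadjusted p under 0.05, and DESeq2 and limma also called 0. The folds lay on either side of 1 depending on the scaling. Without scaling factors they were 1.07, 0.921 and 1.09, in the same order, and by limma on the FPKM values 1.08, 0.958 and 1.15. A further TEM1-like gene, Glyma20g32730.1, had too few counts for the filter: 1, 4 and 3 in DN50 and 12, 23 and 2 in GmRAV1-ox replicates 1 to 3. With no filter its fold was 3.89 (1.07 to 14.1) at an adjusted p of 0.254. Without GmRAV1-ox replicate 3 it was called, with a fold of 5.43 at an adjusted p of 0.0273, and in the fits without 1 DN50 library the adjusted p ranged from 0.254 to 0.479. The summed counts of all 4 genes, before library scaling, were 459 ± 182 in DN50 and 448 ± 75.7 in GmRAV1-ox. With library scaling the fold of the sum was 0.918 (0.589 to 1.43). In the reference table of gene names, the symbol RAV1 sits among 6 neighbours of Glyma01g22260.1, and the symbol RAV belongs to Glyma10g34760.1. Because the 3 tested genes do not show the rise that the group name implies, the groups are called the libraries labelled GmRAV1-ox and DN50 throughout, and each direction below rests on those labels alone.

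**Figure D2:**
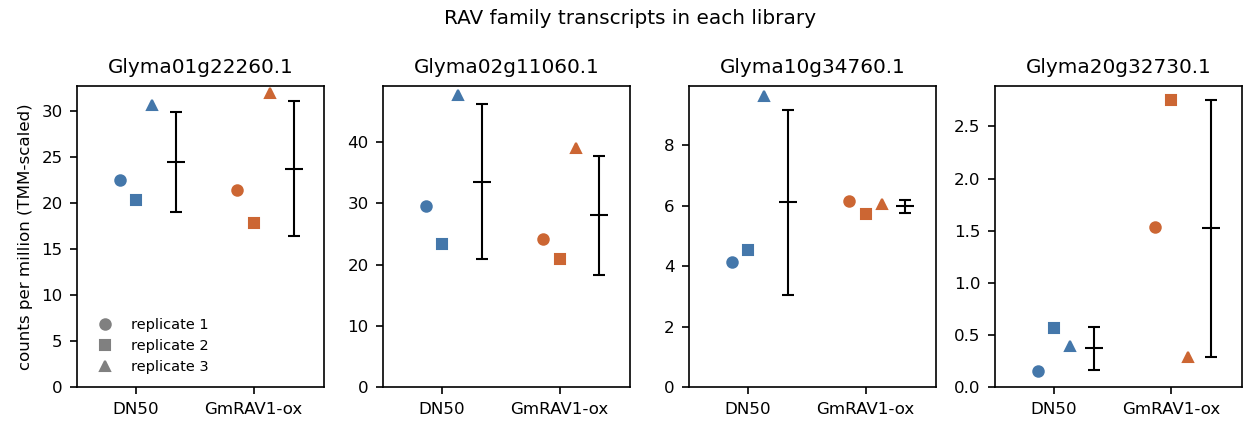
CPM (TMM-scaled) of the 4 RAV family genes in each library, with the y axis from 0 and set per gene. Symbols mark the replicate number, blue DN50 and orange GmRAV1-ox, and the bar beside each group is its mean ± SD. Groups overlap for all 4 genes, with Glyma01g22260.1 at 24.5 in DN50 and 23.7 in GmRAV1-ox. Without scaling factors, and by limma on FPKM, the folds of Glyma01g22260.1 and Glyma10g34760.1 lie above 1 instead of below it.

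The main comparison asked which transcripts differed between the libraries labelled GmRAV1-ox and DN50. Genes with lower transcripts in the libraries labelled GmRAV1-ox included 4 clock genes (1 LHY, 1 CCA1 and 2 PRR95-like), some transporters of nitrate, sulfate, sucrose and inositol, and 1 or 2 genes each for enzymes that break down gibberellin, abscisic acid and cytokinin. The 2 called EARLY FLOWERING 4-like clock genes, a pectate lyase, a beta-galactosidase, a beta-xylosidase and a metal transporter were among those with higher ones. Of 26272 genes tested, 32 were higher and 152 lower in the libraries labelled GmRAV1-ox by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The change was at least 2-fold for 31 of the higher and 148 of the lower genes. Median log2 fold changes were 1.81 among the higher and -1.92 among the lower genes. In all 184, the 3 libraries of one group lay above the 3 of the other, which held for 26% of all tested genes and holds for 10% by chance. At an unadjusted p under 0.05, 2785 genes were higher and 2801 lower, and the smallest adjusted p was 0.0118.

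These counts rested on which libraries entered the fit. Leaving out DN50 replicate 1, DN50 replicate 3, GmRAV1-ox replicate 1 or GmRAV1-ox replicate 2 left 0 calls by edgeR, with 3778, 3509, 3888 and 3290 genes at an unadjusted p under 0.05. Without DN50 replicate 2, 46 genes were higher and 151 lower, with 113 of the 184 among them. Without GmRAV1-ox replicate 3, which lay nearest to DN50 on the first component, 2383 were higher and 2672 lower, with all 184 among them. With no scaling factors, 84 genes were higher and 149 lower, so that 63.9% of calls were lower against 82.6% with TMM, and the median log2 fold change of all genes moved from 0.01 to 0.20. It lay at 0.17 by limma on the FPKM values.

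Among named genes that rose, Glyma17g18010.1, a DMT1 ferrous ion transporter, went from 3.83 ± 0.919 in DN50 to 35.5 ± 21.1 in GmRAV1-ox, 9.26-fold (95% interval 4.38 to 19.6), with a log2 fold change of 3.21 that came to 2.60 without GmRAV1-ox replicate 3. Glyma13g07280.1 rose 7.71-fold and is described as DAO-like, after the dioxygenase that oxidises auxin. Glyma15g02750.1, a beta-galactosidase, rose 5.78-fold. Glyma02g03320.1, a metalloendoproteinase, rose 4.44-fold, and Glyma02g13260.1, a fructokinase, rose 4.35-fold. A beta-xylosidase, Glyma08g19280.1, rose 3.27-fold, and Glyma15g12170.1, described as the fruit protein pKIWI501, rose 3.46-fold. Glyma10g03620.1, LONGIFOLIA 1-like, rose 3.28-fold, and its Arabidopsis namesake promotes elongation of leaf cells. Among those that fell, Glyma08g42500.1, a spermidine hydroxycinnamoyl transferase, went from 37.3 ± 5.43 to 5.38 ± 1.16, 6.92-fold lower (adjusted p 0.0118 by edgeR). Glyma08g12070.1, a chloroplast translocon component, was 8.57-fold lower, and Glyma08g43790.1, a CCCH zinc finger protein, was 6.85-fold lower. Glyma17g14320.1, a geraniol 8-hydroxylase, was 6.18-fold lower, and Glyma09g11120.1, an inositol transporter, was 5.99-fold lower. The SPX-domain gene Glyma09g39920.1, of a family that senses and transports phosphate, was 7.57-fold lower, from 37.3 ± 8.58 to 4.90 ± 1.14. It was the only gene past the threshold among 52 tested phosphate starvation genes, whose median log2 fold change was -0.06. Adjusted over the list alone, 8 of the 52 were lower and 1 higher.

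The naming rule set before the data were examined gave 42 genes past the threshold, 14 higher and 28 lower. With no scaling factors 38 of the 42 were called, and by limma on FPKM, the test first planned, 22. All 42 kept their direction with each library left out. Among them, 21 were called without DN50 replicate 2, 42 without GmRAV1-ox replicate 3, and 0 without DN50 replicate 1, DN50 replicate 3, GmRAV1-ox replicate 1 or GmRAV1-ox replicate 2, where adjusted p ranged from 0.0924 to 0.264. Counts of 16 of the 42 were not whole in at least 1 library, which leaves open how reads shared between gene models were divided. Most of the 14 higher genes are among them, but few of the 28 lower ones. They include Glyma17g18010.1, Glyma13g07280.1, Glyma08g12070.1 and the gibberellin 2-beta-dioxygenase Glyma13g36390.1. Of the clock genes they include CCA1 gene Glyma09g29800.2 and the EARLY FLOWERING 4-like genes Glyma18g03130.1 and Glyma11g35270.1.

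The cytokinin lists were compared because the series title names the hormone. Over 4 lists with 42 tested genes, 1 passed: Glyma11g20860.1, a cytokinin dehydrogenase 6, an enzyme class that degrades cytokinin. It went from 11.5 ± 0.665 in DN50 to 4.17 ± 0.531 in the libraries labelled GmRAV1-ox, a log2 fold change of -1.46 (SE 0.21, adjusted p 0.0363 by edgeR's quasi-likelihood test). Glyma19g33680.1, an isopentenyltransferase 3 of cytokinin synthesis, stood at 5.87 ± 2.17 and 0.193 ± 0.333 (adjusted p 0.0525), from 123 counts in DN50 and 4 in GmRAV1-ox. Glyma11g21650.1, an ARR9-like type-A response regulator, whose class is induced by cytokinin, stood at 17.6 ± 6.05 and 5.89 ± 2.00 (adjusted p 0.0754). With the 4 lists adjusted together and without other genes, 10 genes were lower and 1 higher. Members past the threshold when adjusted over the list alone were 5 lower and 0 higher genes of 19 for synthesis and degradation, 2 lower of 3 type-A regulators, 0 of 11 type-B regulators, and 1 higher and 1 lower of 9 in the list of receptors and phosphotransfer proteins. The 1 higher is neither of these but Glyma11g02140.1, a CRF2-like ethylene-responsive factor (log2 fold change 1.56, adjusted p 0.137 by edgeR over all genes), of a class induced by cytokinin. The 1 lower is the histidine kinase 4-like receptor Glyma05g34310.1 (log2 fold change -0.73).

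The single cytokinin call was not made with any 1 of DN50 replicates 1 to 3 or GmRAV1-ox replicates 1 and 2 left out, which gave 0 calls each. Without GmRAV1-ox replicate 3 there were 17, in both directions. They were 7 lower and 4 higher for synthesis and degradation, 1 lower type-A regulator and 2 lower type-B regulators. The list of receptors and phosphotransfer proteins gave 2 lower and 1 higher. That fit called 2383 higher and 2672 lower genes of 27657. With DESeq2 there were 5 cytokinin calls. In the simulation 32.2% of its calls were unchanged genes, a share that need not hold in the real libraries. Glyma11g20860.1 itself had adjusted p between 0.000239 and 0.215 over 21 alternatives, of which 8 called it, and its log2 fold change stayed between -1.56 and -0.90. The isopentenyltransferase Glyma19g33680.1 was called in 10 of 20 alternatives and the ARR9-like Glyma11g21650.1 in 4 of 21. As a list, synthesis and degradation genes had a median log2 fold change of -0.51 and were lower than other genes by camera (adjusted p = 0.00349, and adjusted p = 0.577 with an estimated correlation). That call was lost without DN50 replicate 1 (0.291, median -0.13), DN50 replicate 2 (0.0762, median 0.04) or GmRAV1-ox replicate 3 (0.259, median -0.21), with no count filter (0.187, median 0.01) with a filter at FPKM 5 (0.0773) and by limma with no filter. The median also moved to -0.26 without DN50 replicate 3 and to -0.29 without GmRAV1-ox replicate 2. By camera, type-B regulators had a median of -0.29 (adjusted p = 0.0717). They were called lower in 6 of 22 alternatives: without DN50 replicate 1 (0.0495), DN50 replicate 2 (0.0366, median -0.43) or GmRAV1-ox replicate 2 (0.0457, median -0.46), with no count filter, and by limma with no filter (0.0203) or quantile normalization (0.0417). The list of receptors and phosphotransfer proteins, which includes 2 CRF2-like factors, had a median of 0.13 (adjusted p = 0.702), and from -0.03 to 0.11 with 1 library left out.

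Clock genes were called in both directions. Of 40 tested, 2 rose and 4 fell in the libraries labelled GmRAV1-ox, and adjusted over the list alone 3 were higher and 17 lower. Those that fell included LHY (Glyma19g45030.1), from 14.4 ± 4.55 to 2.57 ± 1.02, 5.62-fold lower, and CCA1 (Glyma09g29800.2), from 28.6 ± 9.29 to 4.75 ± 2.14, 6.04-fold lower. Both encode MYB-like factors of the morning arm of the plant clock. The other 2 that fell were PRR95-like, Glyma19g44970.1 at 4.05-fold lower and Glyma07g05530.1 at 2.78-fold lower, a pair that lies outside the naming rule and was named after its values were seen. The 2 that rose were EARLY FLOWERING 4-like genes of the evening arm. Glyma18g03130.1 went from 0.951 ± 0.175 to 6.61 ± 0.680, 6.86-fold higher (4.19 to 11.2), and Glyma11g35270.1 from 32.9 ± 7.56 to 80.5 ± 9.81. Other evening genes were not called: the 5 EARLY FLOWERING 3-like genes had log2 fold changes from -0.08 (Glyma07g01600.1) to 0.39 (Glyma04g05280.1), TOC1 gene Glyma06g21120.1 had 1.08, and APRR1-like Glyma04g33110.1 and Glyma05g00880.1 had 0.26 and -0.01. ELF4-like genes Glyma17g05860.1 and Glyma14g37280.1 had -0.54 and 0.34. In the flowering-time list, 1 of 57 genes passed, CONSTANS-LIKE 9-like Glyma14g36930.2, which was 2.58-fold higher. Adjusted over that list alone, 6 were higher and 13 lower.

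As a list the clock genes had a median log2 fold change of -0.36 and were lower than other genes by camera (adjusted p = 3.19e-05, and adjusted p = 0.577 with an estimated correlation). The median came to -0.12 by limma on the FPKM values, where all genes had a median of 0.17. The list call was kept in each of the 6 leave-outs. Flowering-time genes as a list had a median of -0.13 (camera adjusted p = 0.153), of the opposite sign without scaling factors (0.07). Limma called the flowering-time list lower than other genes in 6 of its 8 alternatives, with adjusted p from 0.0203 to 0.0344 and medians above 0.

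**Figure D3:**
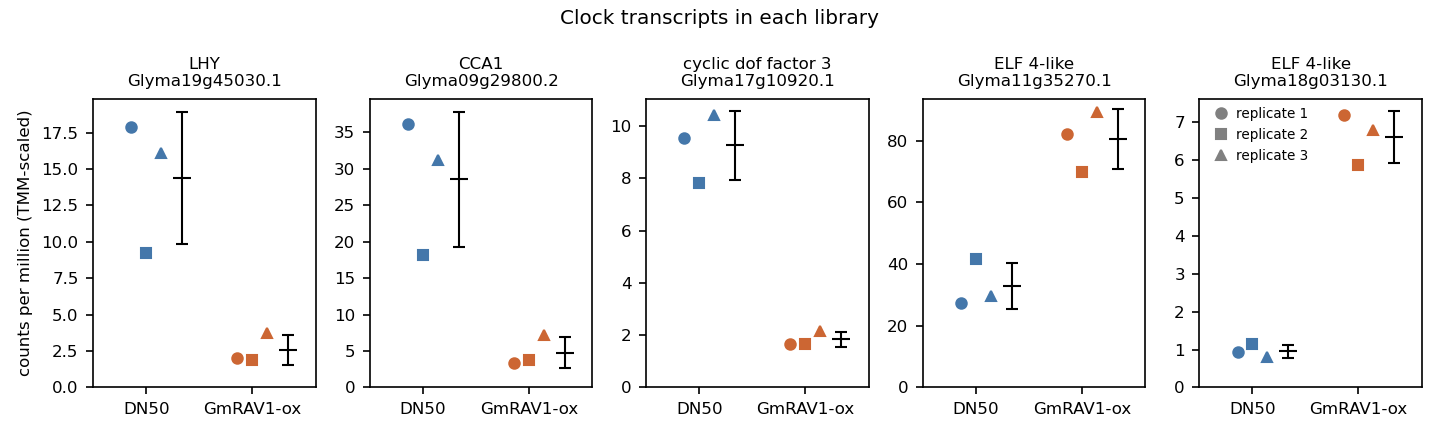
CPM (TMM-scaled) in each library for LHY, CCA1, a cyclic dof factor and 2 EARLY FLOWERING 4-like (ELF 4-like) genes, with the y axis from 0 and set per gene. Symbols mark the replicate number, blue DN50 and orange GmRAV1-ox, and bars are mean ± SD. LHY, CCA1 and the cyclic dof factor are higher in every DN50 library, and both ELF 4-like genes are higher in every GmRAV1-ox library.

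Transport and assimilation of nitrogen and sulfur gave the most called genes of any fixed list. Of 89 tested genes, 7 fell and 0 rose, and adjusted over the list alone 26 were lower and 2 higher. Glyma05g01380.1, a nitrate transporter 1.2, went from 19.2 ± 10.6 to 3.19 ± 0.488, and Glyma11g35890.1, a peptide or nitrate transporter, was 9.90-fold lower. Glyma08g39140.1, a high-affinity nitrate transporter 2.5, had 110 counts in DN50 and 3 in GmRAV1-ox. The ratio was 40.1 with a counting interval (without the spread between libraries) of 13.4 to 197 for this gene. Its fitted log2 fold change of -5.12 came to -5.95 without GmRAV1-ox replicate 1. Sulfate transporters fell as well: Glyma20g02080.1 was 6.73-fold lower, Glyma03g31310.1 was 3.74-fold lower and Glyma02g16370.1 was 2.44-fold lower. The list had a median log2 fold change of -0.58 (camera adjusted p = 2.28e-10, and adjusted p = 0.577 with an estimated correlation). Relative to the DN50 mean, its median stood at -0.66 and -1.01 in GmRAV1-ox replicates 1 and 2. In GmRAV1-ox replicate 3 it stood at -0.11, inside the range of the DN50 libraries.

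Leaf senescence and photosynthesis lists were also lower. All 18 tested genes of chlorophyll breakdown and senescence had lower estimates and 2 of them fell, Glyma04g38690.1, SAG101-like, 4.37-fold, and Glyma11g19800.1, a pheophorbide a oxygenase, 2.49-fold. There were 6 lower genes adjusted over the list alone. By camera the median of -0.82 was called (adjusted p = 4.27e-08, and 0.577 as the adjusted p with an estimated correlation). Neither the 54 light-harvesting and photosystem genes nor the 21 Calvin cycle genes held a call by edgeR, over all genes or adjusted over the list alone, with 6 and 7 lower at an unadjusted p under 0.05. Over all genes 2801 of 26272 were lower at that p, a share near that of the light-harvesting genes. By camera both lists were lower, with medians of -0.33 (adjusted p = 0.000165) and -0.66 (adjusted p = 0.000175), and the adjusted p was 0.583 for both with an estimated correlation. The light-harvesting call of camera was lost with quantile normalization (adjusted p = 0.112, median -0.06). The light-harvesting median was -0.18 without DN50 replicate 1, -0.21 without GmRAV1-ox replicate 2 and -0.60 without GmRAV1-ox replicate 3. The Calvin cycle median was -0.40 without DN50 replicate 1 and -0.88 without GmRAV1-ox replicate 3. Relative to the DN50 mean, GmRAV1-ox replicate 3 stood at -0.01 for light harvesting and -0.16 for the Calvin cycle, both inside the range of the DN50 libraries. Replicates 1 and 2 stood at -0.39 and -0.70 for light harvesting and at -0.61 and -1.01 for the Calvin cycle.

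Genes of other hormones differed in several places. A gibberellin 2-beta-dioxygenase 8, Glyma13g36390.1, of a class that inactivates gibberellin, went from 5.81 ± 1.47 to 0.187 ± 0.223, 30.2-fold lower, from 121 counts in DN50 and 4 in GmRAV1-ox. Its log2 fold change of -4.92 came to -4.32 without GmRAV1-ox replicate 2 and -6.22 without GmRAV1-ox replicate 3. A related gene, Glyma11g00550.1, was 2.01-fold lower. These were the 2 called of 34 gibberellin genes (3 lower when adjusted over the list alone), whose median of 0.12 had the opposite sign to the direction of camera (adjusted p = 0.337). That median ranged from 0.00266 to 0.193 with 1 library left out. The third lower gene was Glyma13g43850.1, a gibberellin 3-beta-dioxygenase 1 and not a 2-beta-dioxygenase, 2.93-fold lower (adjusted p 0.0525 by edgeR over all genes). It lies outside the naming rule and was named after its values were seen. Of 41 abscisic acid genes, 2 fell: Glyma09g41960.1, an abscisic acid 8'-hydroxylase, which catabolises the hormone, 3.02-fold, and Glyma14g32430.1, a protein phosphatase 2C, 4.35-fold. The list held 8 lower and 1 higher gene adjusted over the list alone, and its median was -0.39 (camera adjusted p = 0.00312, and adjusted p = 0.577 with an estimated correlation), or -0.205 without DN50 replicate 3. That median of the abscisic acid genes was -0.17 with no count filter, -0.22 with no scaling factors and between -0.30 and -0.00143 by limma, nearest 0 with no filter, and the list was called in each. Of 59 auxin transport and ARF genes, 1 rose, the auxin response factor 9-like Glyma07g16170.1, 3.69-fold. It was also the only one adjusted over the list alone. That list had a median of 0.24 (camera adjusted p = 0.0185, and adjusted p = 0.583 with an estimated correlation), and its call was lost without DN50 replicate 1 (0.118) or GmRAV1-ox replicate 1 (0.108) and with a filter at FPKM 5.

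Among 103 flavonoid and phenylpropanoid genes, 4 fell. The 4-coumarate:CoA ligases Glyma17g07190.1, 3.90-fold lower, and Glyma13g01080.1, 2.48-fold lower, act at the entry of phenylpropanoids into flavonoid and lignin synthesis. Glyma13g06230.1, an isoflavone malonyltransferase, was 2.20-fold lower. Glyma12g15870.1, an anthocyanidin glucosyltransferase, had 82 counts in DN50 and 0 in GmRAV1-ox, at least 29.9-fold lower against a floor of 3 counts over the group. Another adjustment, over the list alone, gave 10 lower and 1 higher. The median was -0.23 (camera adjusted p = 0.00901, and adjusted p = 0.577 with an estimated correlation), and the call was lost without GmRAV1-ox replicate 3 (0.237) and with array weights in limma (0.0782, median 0.14). The flavonoid median was -0.09 without DN50 replicate 3 and -0.35 without GmRAV1-ox replicate 1.

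For cell walls, 1 of 161 tested genes rose and 2 fell. The riser was pectate lyase Glyma18g38430.1, at 4.39-fold, and the others were the cellulose synthase-like genes Glyma14g01670.1, 4.79-fold lower, and Glyma14g01660.1, 7.04-fold lower. Adjusted over the list alone, 9 were higher and 7 lower, and the list was not called by camera (median 0.34, adjusted p = 0.0934). It was called higher without DN50 replicate 2 (0.0157) or GmRAV1-ox replicate 3 (0.00115), by DESeq2 and with the replicate number as a block. Among 60 sugar and starch genes, sucrose transporter Glyma10g36200.1 was 3.66-fold lower and beta-amylase Glyma11g04210.1 was 3.06-fold higher. Of these 60, 9 were lower and 1 higher adjusted over the list alone. The sugar list had a median of -0.27 (camera adjusted p = 0.00349, and adjusted p = 0.577 with an estimated correlation), lost without GmRAV1-ox replicate 3 (0.0736), and the median was -0.17 without DN50 replicate 1 and -0.14 without GmRAV1-ox replicate 2. Of 171 NBS-LRR resistance genes 0 were called by edgeR, over all genes or adjusted over the list alone, with 21 lower and 1 higher at an unadjusted p under 0.05. Over all 26272 genes 2801 were lower and 2785 higher at that p. The lower share of the NBS-LRR genes was thus near that of all genes, and their higher share was below it. The NBS-LRR median was -0.25 (camera adjusted p = 0.000805, and adjusted p = 0.583 with an estimated correlation), lost without DN50 replicate 3 (0.0527, median -0.14), and the median was -0.44 without GmRAV1-ox replicate 3.

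Lists of protein synthesis and cell division were higher without a called member. Ribosomal proteins (259 tested) had a median log2 fold change of 0.56 (camera adjusted p = 1.22e-18, and adjusted p = 0.577 with an estimated correlation), with 104 higher and 0 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone. Core histones (17 tested) had a median of 1.38 (camera adjusted p = 2.65e-08, and adjusted p = 0.577 with an estimated correlation), and adjusted over the list alone 14 were higher. Cell-division genes (143 tested) had a median of 0.37 (camera adjusted p = 0.000356, and adjusted p = 0.577 with an estimated correlation), with 0 adjusted over the list alone and 38 higher and 5 lower by edgeR at an unadjusted p under 0.05. In GmRAV1-ox replicate 3 the median of the cell-division genes stood at 0.00 relative to the DN50 mean, against 0.44 and 0.56 in replicates 1 and 2. Without GmRAV1-ox replicate 3 the cell-division median was 0.88, with 82 genes higher by edgeR, and with a filter at FPKM 5 the list call was lost (0.0544, median 0.11). The cell-division median was also 0.64 without DN50 replicate 1, 0.79 without DN50 replicate 2 and 0.21 without GmRAV1-ox replicate 2. Without GmRAV1-ox replicate 2 the histone median was 0.74, and without DN50 replicate 3 the ribosomal median was 0.365.

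Across all lists, camera with its preset correlation called 14 of 35, 4 higher and 10 lower, and 9 of the 14 were called in each of the 6 leave-outs. With an estimated correlation 0 were called, and by fry 0 after adjustment and 8 at an unadjusted p under 0.05. The median of each of the 14 had the same sign under every scaling tried, but those of the lower lists lay nearer 0 where the scaling moved all genes upward. Without scaling factors and by limma on FPKM, in that order, the medians were -0.08 and -0.07 for NBS-LRR genes, -0.05 and -0.03 for flavonoid genes, -0.16 and -0.12 for light-harvesting genes, and -0.09 and -0.12 for sugar genes. They were -0.47 and -0.41 for Calvin cycle genes, -0.40 and -0.36 for nitrogen and sulfur genes, -0.19 and -0.12 for clock genes, and 0.43 and 0.38 for auxin transport and ARF genes. The cell-division median was 0.77 with no count filter, 0.20 by limma with median-of-ratios scaling and 0.19 with quantile normalization. The 9 other splits of the same 6 libraries called 5 to 18 lists, the most with DN50 replicate 2 and GmRAV1-ox replicate 3 exchanged. Lists not called had adjusted p from 0.0545 for heat shock proteins (median -0.24) to 0.997 for Aux/IAA, GH3 and SAUR genes (median -0.18). A list whose members move both ways can go uncalled by camera. Adjusted over the list alone, 9 of 38 Aux/IAA, GH3 and SAUR genes were higher and 6 lower, and 5 of 30 brassinosteroid genes were higher and 0 lower. The heat shock list was called lower than other genes in 13 of 22 alternatives, among them all 8 by limma (0.00876 to 0.0345), no scaling factors (0.0254), the replicate number as a block, and the fits without DN50 replicate 2 (0.0366), GmRAV1-ox replicate 1 (0.0483) or GmRAV1-ox replicate 3 (0.025). Among the lists not called, jasmonate genes had a median of -0.29 (0.0934), ethylene genes -0.19 (0.153), brassinosteroid genes -0.02 (0.313), phosphate starvation genes -0.06 (0.397), ERF factors 0.14 (0.223), WRKY factors -0.15 (0.246), pathogenesis-related proteins 0.15 (0.213) and drought-response genes -0.07 (0.257). The jasmonate list was called lower in 7 of 22 alternatives, among them the fits without DN50 replicate 1 (0.0465) or GmRAV1-ox replicate 1 (0.0018). With 1 library left out, the jasmonate median ran from -0.421 to 0.0215 and the ethylene median from -0.253 to -0.0307. Pathogenesis-related proteins were called higher without DN50 replicate 2 (0.0456), DN50 replicate 3 (0.0484) or GmRAV1-ox replicate 3 (0.00416). Ethylene genes were called lower without DN50 replicate 2 (0.0465), WRKY factors lower without DN50 replicate 1 (0.0473) and ERF factors higher with no count filter (0.0395). Shoot meristem and organ boundary genes had a median of -0.06 (0.61), or -0.14 (0.408) with unrelated matches removed from the list. Markers of other tissues were not called either: seed storage proteins 1.07 (0.0816), phloem and xylem -0.32 (0.0934), pollen and flower 0.26 (0.107), root and nodule -0.03 (0.937) and epidermis -0.01 (0.386). The calls of some depended on single libraries. Seed storage proteins had medians from 0.435 to 2.36 in the leave-outs and were called higher without DN50 replicate 2 (median 2.36, 0.0011) and with the replicate number as a block (0.00066). Phloem and xylem markers ranged from -0.621 to -0.0525 and were called lower in 6 of 22 alternatives, among them the fit without GmRAV1-ox replicate 1 (median -0.621, 0.000242). Root and nodule markers were called higher without GmRAV1-ox replicate 3 (median 0.406, 0.00234) and epidermis markers higher without DN50 replicate 2 (median 0.105, 0.0399). The 2 vegetative storage proteins were too few for camera and not called by edgeR, at 39.7 ± 47.9 in DN50 and 871 ± 755 in GmRAV1-ox for Glyma07g01730.1 (adjusted p 0.15) and at 1.22 ± 0.703 and 27.9 ± 22.1 for Glyma08g21410.1 (adjusted p 0.0981). Both were higher when adjusted over the list alone.

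**Figure D4:**
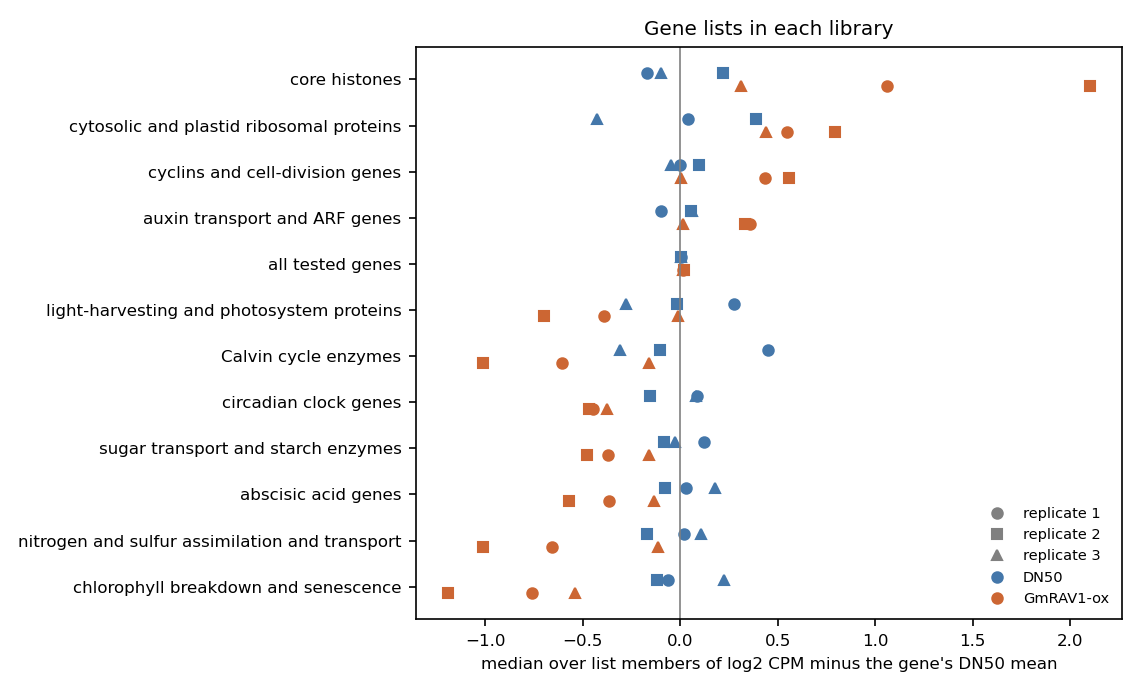
Median over the members of each list of log2 CPM minus each gene's DN50 mean, 1 point per library. Blue points are DN50, orange points are GmRAV1-ox and symbols mark the replicate number. Core histones reach 2.10 in GmRAV1-ox replicate 2 and 0.31 in replicate 3.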

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

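The fits with no scaling factors and the GO terms were chosen after the results were seen. Of 32 genes higher and 152 lower, DESeq2's Wald test gave 665 and 1042 (in the simulation 32.2% of its calls were unchanged genes), no count filter 62 and 231, and no scaling factors 84 and 149. Limma on FPKM gave 43 and 90, or 45 and 89 with a pseudocount of 0.5, 20 and 54 with 0.1, 6 and 5 with no filter, 10 and 37 with median-of-ratios scaling, 6 and 9 with quantile normalization, 13 and 21 with neither trend nor robust estimation, and 5860 and 2296 with array weights. The replicate number as a block gave 682 and 939 and 5 cytokinin genes. The replicate numbers are not known to pair the samples: deviations of same-numbered libraries correlated at -0.301, 0.398 and 0.295, and 4 of 6 libraries correlated best with their own number, a hint at most. Leaving out 1 library gave 0 to 2383 higher genes, 0 to 2672 lower, 0 to 1 RAV genes, 0 to 17 cytokinin genes and 14 to 20 lists. The 0 calls came without DN50 replicate 1 or 3 or GmRAV1-ox replicate 1 or 2 (edgeR, 3290 to 3888 genes at an unadjusted p under 0.05), and the highest counts without GmRAV1-ox replicate 3. Cytokinin genes called, 1 by edgeR, were 5 by DESeq2, 2 with no count filter, 18 with array weights, and 0 by limma with a pseudocount of 0.1, no filter or quantile normalization. Lists called, 14 with preset correlation, were 0 with an estimated correlation and 0 by fry. The other counts under these settings (61) stayed within 1.5 times. Taken gene by gene and setting by setting, named genes kept direction and side of the threshold 547 times, lost the call 413 times and gained it 14 times, and lists did so 690, 29 and 52 times. None reversed, with a list's direction read from camera relative to all genes and uncalled results that changed sign counted as kept. Medians still crossed 0 for cytokinin synthesis, degradation and conjugation (0.01 with no count filter, 0.06 by limma with no filter, 0.04 without DN50 replicate 2), for flavonoid and phenylpropanoid enzymes (0.03 by limma with no filter, 0.14 with array weights) and for sugar transport and starch enzymes (0.00 by limma with no filter). The causes were not tested. In the simulation edgeR recovered 9.68% of 2-fold changes. Depth, spread and the number of changed genes were not varied apart there, so neither this share nor the 32.2% of DESeq2 need hold for the real libraries.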

Other observations

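The tests in this part were chosen after the results were seen, except the count of genes on in 1 group and off in the other and the length test of the ribosomal list, and the genes in the next paragraph were picked after their values were seen.

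Several genes outside the fixed lists fell. Benzyl alcohol O-benzoyltransferase Glyma03g40430.1 went from 91.0 ± 10.7 in DN50 to 15.98 ± 1.86 in the libraries labelled GmRAV1-ox (edgeR adjusted p 0.0118). Amino-acid permease BAT1 homologs fell, Glyma10g41560.1 from 60.7 ± 6.68 to 16.1 ± 2.13 and Glyma20g25670.1 from 23.4 ± 1.89 to 7.33 ± 0.588. Chlorophyllide a oxygenase, which makes chlorophyll b, fell at Glyma13g03430.1 (116 ± 37.0 to 26.2 ± 4.91) and Glyma14g23860.1 (42.2 ± 15.9 to 8.71 ± 1.85). A GLK1-like gene, Glyma13g37010.1, of a family that activates chloroplast genes, went from 77.7 ± 6.82 to 28.5 ± 4.56. Cu-Zn superoxide dismutases Glyma19g42890.2 (37.9 ± 12.04 to 9.25 ± 1.14) and Glyma11g19840.1 (242 ± 112 to 48.8 ± 3.62) fell as well. COP1-like Glyma14g05430.1, of a light-signalling ligase, went from 15.1 ± 5.61 to 3.51 ± 0.981.

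Of 438 GO terms, camera called 31 higher and 47 lower, and 0 with an estimated correlation (adjusted p = 0.804 for the called terms below). Nucleosome assembly had a median of 0.96 (adjusted p = 1.31e-11). Lower terms included myo-inositol hexakisphosphate biosynthetic process (median -0.90, 6.67e-07), amino acid transmembrane transport (-0.60, 1.69e-06) and light harvesting (-0.61, 3.2e-06). Chlorophyll catabolic process (-0.615, 2.64e-05) and two-component signal transduction (-0.395, 6.71e-06) were also lower. Circadian rhythm (-0.112, 0.262), response to cytokinin stimulus (-0.04, 0.62) and leaf senescence (-0.08, 0.156) were not called. The call of the fixed clock list was thus not repeated by the circadian rhythm term. Genes on in 1 group and off in the other numbered 6. Apart from those in the report, these were Glyma03g25030.1, a hydroquinone glucosyltransferase with 3 counts in DN50 and 266 in GmRAV1-ox (ratio 81.1, counting interval 27.4 to 396), Glyma18g05410.1 (3 and 68, 20.7, 6.8 to 103), Glyma06g07780.1 (46 and 3, 16.8, 5.39 to 84.3) and Glyma07g04460.1 (84 and 1, 91.9, 16 to 3670).

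The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.1. The labelled split called 184 genes and the highest of the others 77, so 1 of 10 gave as many. For cytokinin genes these values were 1 and 0, again 1 of 10 splits. For lists they were 14 and 18, so 3 of 10 gave as many.

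None of the 3 RAV transcripts that passed the filter was higher in the libraries labelled GmRAV1-ox; a rise of the fourth, Glyma20g32730.1, whose low counts barely enter the sum, stays open (fold 3.89, 1.07 to 14.1, adjusted p 0.254 with no filter, and 5.43, adjusted p 0.0273, without GmRAV1-ox replicate 3). Reads of an added copy spread over related genes could hide a rise, but the summed counts had an upper 95% limit of 1.43-fold, and Glyma01g22260.1 alone had 1.45, which argues against a 2-fold rise of the sum or of that gene. In DN50, Glyma01g22260.1 and Glyma02g11060.1 stood at 24.5 and 33.5 CPM and Glyma10g34760.1 at 6.11. The sum thus says little about a spread rise that is large only against the level of Glyma10g34760.1. A swap of 1 library of each group could also hide one: over the 9 exchanges the highest upper limit was 1.97 for Glyma01g22260.1, just under a bound of 2 chosen after the values were seen, but 2.44 for Glyma02g11060.1 or Glyma10g34760.1 (GmRAV1-ox replicate 2 with DN50 replicate 3), which leaves those open. The count of on-off genes met the prediction for a swap, 14 with DN50 replicate 2 and GmRAV1-ox replicate 3 exchanged against 6 as labelled, but that exchange called 77 genes against 184 (a ground for leaving the swap open that was decided after the values were seen) and gave RAV folds of 0.701, 0.588 and 0.827 with upper limits of 0.943, 0.812 and 1.41, so it hides no 2-fold rise of these 3 genes. Whether the plants carried a transgene whose transcript the gene models do not count was not tested.

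Of the clock genes, 1 LHY, 1 CCA1 and 2 PRR95-like genes fell and 2 EARLY FLOWERING 4-like genes rose in the libraries labelled GmRAV1-ox. A shift of all genes by library scaling would move all genes the same way. The 95% intervals of the 2 called LHY and CCA1 genes and of the 2 called EARLY FLOWERING 4-like genes lay 2.48 apart (log2). These genes were picked as called in opposite directions, so a gap above 0 was set by the choice and cannot decide the question. Under the scalings tried the median of all genes moved between 0.01 and 0.20, while LHY gene Glyma19g45030.1 stayed between -2.50 and -1.65 (not called under the 3 scalings of FPKM values) and EARLY FLOWERING 4-like gene Glyma18g03130.1 between 2.55 and 2.96. A harvest at another time of day may account for the called genes: the 5 cyclic dof factor genes, with a morning peak in other plants, had a median of -1.29 (2 called) and lay on the side of LHY and CCA1. The prediction was that genes of each phase move together. The 7 EARLY FLOWERING 4 and TOC1 genes had a median of 0.34, with 2 called and 2 with lower estimates, so they did not all do so. An effect of genotype on the clock would look like a change of harvest time. Harvest times are not in the labels, so harvest time and genotype cannot be told apart here.

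Ribosomal protein, core histone and cell-division lists were higher by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.577 for each) or by fry (adjusted p from 0.219 to 0.276). Coding length could bias such lists, but the medians of 0.56, 1.38 and 0.37 lay above the highest of 1000 lists matched on length and expression, 0.104, 0.687 and 0.169. Leaves at a younger stage in some libraries could give the pattern. The prediction for this was that the medians of GmRAV1-ox replicate 3 lie within the range of the DN50 libraries. That was met for cell division (0.00). It was not met for 2 of the 3 lists, ribosomal (0.44, highest DN50 library 0.386) and histones (0.31, highest DN50 library 0.22), so the explanation stays open. Leaf stage and genotype were not separated by the design, and an effect of the GmRAV1 genotype on growth remains untested.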
